A study of Mus musculus with 15 samples.

How the data were processed

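RNA was measured by sequencing in CD45-negative cells from mouse ankle joints, 22 days after infection with Borrelia burgdorferi, the Lyme disease spirochaete. CD45 is the surface protein carried by nearly all leukocytes, so its removal on magnetic beads leaves mainly the resident cells of the joint. The 3 strains compared were B6 (the control) and the congenic lines ISRCL4 and ISRCL3, with 5 libraries each. Per the labels, each library pools the cells of 2 mice, so the replicates of a strain are separate pools; nothing else in the labels gives their origin. Per the labels' protocols, RNA was recovered with TRIzol, cleaned on Direct-zol columns, enriched for polyadenylated transcripts and read on an Illumina HiSeq as 50-cycle single reads. Trimming, alignment settings and the handling of duplicate reads are not given in the sources used here.

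The files hold raw counts per gene as the authors deposited them, 1 file per library, with no normalization and no filter on genes. Per the file headers, the counts came from featureCounts 1.5.0-p3 with strand setting 2 (reverse-strand counting) over the exons of each gene in the Ensembl release 87 annotation of the mouse genome GRCm38; reads that fell on several genes or several places were not counted, since the command carried neither option for them. Per the submitters' processing notes, reads were aligned with STAR 2.5.2b to GRCm38, and DESeq2 was used, with no version given. Polyadenylated, single-end libraries suit gene counts of this kind; genes with close copies lose reads that map to several places. The counts of the 15 libraries were whole numbers with totals of 13280319 to 17717636. Of the 49671 genes in the files, 49326 were matched to a symbol and 345 were not, and 19218 had no count in any library. A count of 3 corresponded to 0.169 to 0.226 CPM (counts scaled to a common library size), which is the floor used here for genes near 0. Floors cover counting error only, since the libraries carried no molecular identifiers.

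Genes were filtered with edgeR's filterByExpr by strain, which left 15301 genes, and libraries were scaled by the trimmed mean of M values (factors 0.964 to 1.03). Strains were compared with edgeR 4.0.16 in R 4.3.3, in 1 robust quasi-likelihood fit to all 15 libraries, with two-sided tests and Benjamini-Hochberg adjustment at 0.05. Each sample title opens with 1 of 2 numbers. All B6, all ISRCL4 and 2 ISRCL3 libraries (replicates 1 and 2) carried the first prefix and 3 ISRCL3 libraries (replicates 3 to 5) the second. The labels do not say what the prefix means; it was taken as a possible batch and kept as a term. With that term, ISRCL3 estimates rest on the 2 libraries of the first prefix. Counts of changed genes are also given without it, as are values of part of the genes and lists. Counts of changed genes are calls at adjusted p under 0.05. Values per library are CPM on the scaled library sizes, given as mean ± SD with n = 5 unless stated; log2 fold changes carry ± standard error.

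The genes named were set by a rule. Mstn, Ifnb1 and Ptprc were always reported. For each line against B6, the 12 largest rises and the 12 largest falls among called genes with an average log2 CPM of at least 0 and a proper symbol were taken (8 and 8 between the lines); with fewer than 5 in a direction, the 5 smallest p-values were given as values. Up to 4 members with the smallest p were taken from each list that passed, up to 3 from the interferon cluster, type I interferon response, myostatin, muscle and leukocyte lists in any case, and up to 10 called genes from a chromosome enriched for calls. Not every gene that the rule takes is named in the text or drawn. The groups, the tests, this rule, the gene lists and most alternatives were set before the data were examined.

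The 23 gene lists were interferon cluster, type I interferon response, interferon gamma response, myostatin and activin pathway, skeletal muscle fibre, satellite cell and myoblast, fibroblast and synovial lining, endothelial cell, pericyte and smooth muscle, chondrocyte, osteoblast and bone, osteoclast, tendon cell, adipocyte, Schwann cell, keratinocyte, leukocyte, erythroid, inflammatory cytokines and chemokines, matrix proteases, proliferation, dissociation stress, and sex linked. They were tested with camera (preset correlation of 0.01, and again with an estimated correlation) and with fry in limma 3.58.1, adjusted over the lists within a comparison. Unless called mixed, fry here means its directional test. The mixed test of fry, which takes changes in either direction, was run as well. A list score is the mean log2 CPM of its members (prior count 2) minus the B6 mean. Calls per chromosome were compared with all tested genes by Fisher's exact test, two-sided, adjusted over chromosomes.

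Because both lines were set against the same B6 libraries, agreement between the lines was compared with 20 simulations of unchanged groups against shared controls, and with the B6 libraries divided 3 and 2. The alternatives tried were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, a stricter filter (CPM of 1 in 5 libraries), no prefix term, only first-prefix libraries, only the strains compared, muscle and erythroid genes left out, limma voom with sample weights, and each library left out in turn. Dixon's ratio on the muscle and keratinocyte scores named no library. Libraries standing apart were taken as those with a muscle or keratinocyte score more than 1.5 above the B6 mean; this and the fit with a leukocyte score were added after the data were seen. The procedure was tested on simulated data, where it recovered 70% of genes changed 1.5-fold and 82% of those changed 2-fold for ISRCL4 against B6, 50% and 68% for ISRCL3 against B6, and 44% and 76% between the lines, with 4.49%, 5.62% and 4.49% false calls. Genes were drawn independently there, and only genes with an average log2 CPM above 0 were changed. The simulated libraries lack any structure of the real samples, so these shares may not hold for them. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. No library was left out of the main comparisons.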

Results

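Transcripts were counted in 15 libraries of CD45-negative ankle joint cells taken 22 days after infection with Borrelia burgdorferi, 5 each from B6, ISRCL4 and ISRCL3 mice. Totals ran from 13280319 counts (B6 replicate 4) to 17717636 (ISRCL4 replicate 4), and 21772 to 22917 genes had at least 1 count in a library. The 10 most abundant genes took 8.32% to 10.29% of counts and mitochondrial genes 2.14% to 4.64%. The first principal component held 21.7% of the variance. Replicates within each strain differed by more than sampling noise, so none was a copy of another. Leukocyte transcripts remained after the CD45 depletion. Ptprc, which encodes CD45, stood at 180 ± 64.4 CPM in B6, 182 ± 49.0 in ISRCL4 and 135 ± 14.9 in ISRCL3 (SD, n = 5). As background, the lines come from work on Bbaa1, an arthritis-associated locus on chromosome 4 that spans the type I interferon gene cluster, and that work has also dealt with myostatin. The question of each comparison is which joint-cell transcripts differ between the strains during infection.

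In ISRCL4, myostatin (Mstn, ENSMUSG00000026100, chromosome 1, 53061640 to 53068079), a secreted factor that restrains muscle growth, rose 3.06-fold against B6, from 2.88 ± 0.26 to 8.80 ± 1.36 CPM (log2 1.61 ± 0.157, adjusted p = 0.000336, edgeR's quasi-likelihood test). Cartilage matrix genes fell. Col10a1, the collagen of hypertrophic cartilage, went from 149 ± 67.4 to 39.0 ± 9.71 CPM (adjusted p = 0.029) and Col2a1, the main cartilage collagen, from 137 ± 58.5 to 46.1 ± 7.61 (adjusted p = 0.0351). Acan, the cartilage proteoglycan aggrecan, went from 97.9 ± 16.0 to 55.3 ± 12.2 CPM (adjusted p = 0.0345). Of 22 alternative settings, 12 ended the call of Col10a1, 15 that of Col2a1 and 12 that of Acan, all with the same direction. With 1 library left out, Col2a1 stayed called only without B6 replicate 3, Col10a1 only without B6 replicate 1, 3 or 4, and Acan only without B6 replicate 3 or ISRCL4 replicate 1. Enzymes of cholesterol synthesis were among the genes that fell, with Cyp51 at -0.66 ± 0.0875 (adjusted p = 0.00369), Sqle at -0.66 ± 0.102 (adjusted p = 0.0123) and Fdft1 at -0.64 ± 0.108 (adjusted p = 0.0178) on the log2 scale. Their regulator Srebf2 fell too (-0.49 ± 0.074, adjusted p = 0.00875), while the cholesterol exporter Abca1 rose from 256 ± 18.1 to 358 ± 29.6 CPM (adjusted p = 0.0172).

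In all, 56 of 15301 genes passed, 20 higher and 36 lower in ISRCL4, and 1775 had an unadjusted p under 0.05. All 5 libraries of a strain lay apart from all 5 of the other for 461 genes, 3.01% of those tested, where chance gives 0.794%. Among the other rises, the glycosyltransferase gene Galnt15 went from 368 ± 53.0 to 624 ± 47.0 CPM (adjusted p = 0.00583). The endosomal adaptor gene Wdfy1 went from 33.5 ± 1.45 to 55.9 ± 7.41 (adjusted p = 0.000862), and the mitochondrial transhydrogenase gene Nnt from 14.5 ± 2.57 to 29.2 ± 7.66 (adjusted p = 0.0221). The transcription factor Klf15 (0.98 ± 0.195) and the cysteine dioxygenase Cdo1 (0.81 ± 0.15) rose as well. Of 22 alternative settings, 11 ended the call of Nnt, 14 that of Klf15 and 11 that of Cdo1. Smaller rises were found for Kcns3, Aox1, Mme and Mettl7a1, whose calls ended in 13, 12, 12 and 14 of the 22. Among the other falls, the insulin-degrading enzyme Ide went from 109 ± 8.87 to 64.4 ± 8.89 CPM (adjusted p = 0.000862) and Evi5l from 39.0 ± 3.77 to 21.4 ± 2.07 (adjusted p = 0.00349). Gdf6, a bone morphogenetic protein of joint development, fell by 1.10 on the log2 scale, Fibcd1 fell by 1.28, Clec3a, a lectin known from cartilage, fell by 0.82 and Rab11fip4 fell by 0.70. The calls of Gdf6, Clec3a and Rab11fip4 ended in 12, 4 and 13 of the 22 settings, and that of Fibcd1 in 10 of 21. Galnt15, Wdfy1, Ide and Evi5l stayed called in all 22. Tnfrsf11b, which encodes the osteoclast inhibitor osteoprotegerin, fell from 50.8 ± 6.95 to 34.5 ± 2.33 CPM (adjusted p = 0.0172).

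**Figure D1:**
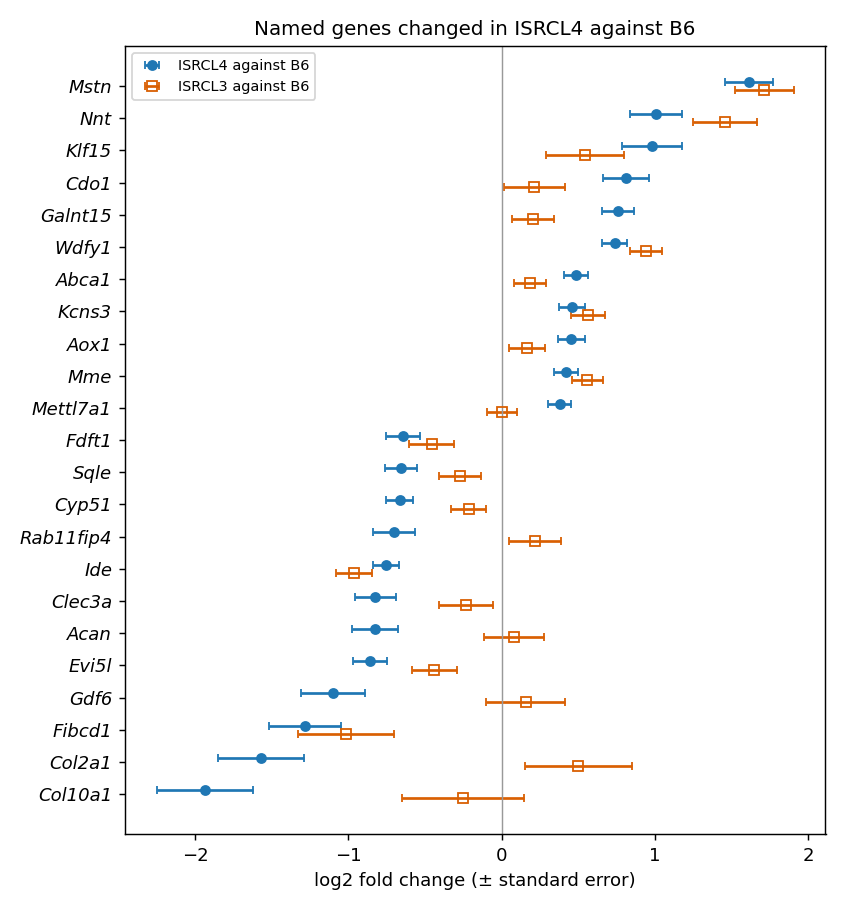
Log2 fold change (horizontal axis) of the named genes changed in ISRCL4 against B6, with standard errors as bars; filled circles are ISRCL4 against B6 and open squares the same genes in ISRCL3 against B6. Mstn stands highest in both lines, at 1.61 and 1.71, while Col2a1 stands at -1.57 in ISRCL4 and 0.50 in ISRCL3.

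Cartilage and tendon genes were lower as groups in ISRCL4 with camera's preset correlation alone. Neither list passed with an estimated correlation or in directional fry (fry adjusted p = 0.0858 and 0.098). In mixed fry, which does not test for a common direction, both passed (adjusted p = 0.00639 and 0.0363). Of 13 measured chondrocyte genes, 3 fell over all genes tested and 9 adjusted over the list alone, with a median log2 fold change of -0.61. The list passed camera (adjusted p = 2.626e-17) but was lost with the correlation estimated (adjusted p = 0.177 with an estimated correlation). Of 10 tendon genes edgeR called 0 over all genes, with 6 lower at an unadjusted p under 0.05 and 6 adjusted over the list alone (median -0.33). This list passed camera too (adjusted p = 5.248e-07; adjusted p = 0.197 with an estimated correlation), and its members with the smallest p were Cilp2 (-0.47), Cilp (-0.44), Scx (-0.47) and Tnmd (-0.34). The adipocyte list had a median of -0.78 (camera adjusted p = 0.000916; adjusted p = 0.306 with an estimated correlation). Of its 9 members 1 was lower adjusted over the list alone, Adipoq having the smallest p (6.88 ± 2.09 against 4.00 ± 0.83 CPM).

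Interferon-induced genes were lower as a group in ISRCL4 with camera's preset correlation alone, none of them passing singly. The type I and gamma lists passed neither with an estimated correlation nor in directional fry (fry adjusted p = 0.0992 and 0.146). In mixed fry the type I list passed (adjusted p = 0.0469) and the gamma list did not (adjusted p = 0.108). All 37 measured members of the type I interferon response list had negative log2 fold changes (median -0.43). In edgeR 0 passed over all genes tested, 24 were lower at an unadjusted p under 0.05 and 17 were lower adjusted over the list alone. The list passed camera (adjusted p = 2.336e-22; adjusted p = 0.197 with an estimated correlation). Among the members with the smallest p-values were Xaf1 (-0.43, adjusted p = 0.0891), Ifi213 (-1.14) and Irf9 (-0.33). All 28 interferon gamma response genes were negative too (median -0.50), with 0 called over all genes, 9 at an unadjusted p under 0.05 and 3 adjusted over the list alone. This list also passed camera (adjusted p = 4.968e-13; adjusted p = 0.279 with an estimated correlation), Psmb8 (-0.49), Tap1 (-0.49), Psmb9 (-0.44) and Igtp (-0.69) having the smallest p.

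Of the interferon cluster on chromosome 4 only 5 genes were abundant enough to test. Klhl9 (88718292 to 88722465), a ubiquitin ligase adaptor beside the interferon genes, fell from 59.4 ± 3.55 to 43.2 ± 3.31 CPM (adjusted p = 0.00661), the 1 call over all genes and the 1 adjusted over the list alone. Hacd4 (0.28) and Mtap (0.10) did not pass, nor did the list (camera adjusted p = 0.68), whose median was positive (0.10) while the test pointed down. Ifnb1, the interferon beta gene (chromosome 4, 88522025 to 88522774), had 2 counts in 1 ISRCL4 library and none in B6 or ISRCL3, so a difference was not detectable at this depth.

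Mstn was the 1 gene of the 23 in the myostatin and activin list to pass over all genes, 3 being higher adjusted over the list alone (median 0.09). The list passed camera (adjusted p = 0.00208; adjusted p = 0.304 with an estimated correlation), and Acvr2a (0.19), Fbxo32 (0.29) and Inhba (-0.33) did not pass over all genes. Skeletal muscle fibre genes had a median of 0.25, with 0 of 25 called by edgeR, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.00208; adjusted p = 0.727 with an estimated correlation). Mb (0.62), Tcap (0.56), Eno3 (0.27) and Xirp2 (0.44) had the smallest p there. The lists for pericytes (median -0.17), osteoblasts (0.16), erythroid cells (-0.29), cytokines (-0.15), matrix proteases (0.16) and proliferation (-0.12) passed with the preset correlation. Each was lost, with an adjusted p of 0.609, 0.72, 0.727, 0.727, 0.609 and 0.727 with an estimated correlation. The erythroid list did not pass without the prefix term (camera adjusted p = 0.0642). The leukocyte list did not pass (median -0.05, camera adjusted p = 0.817), nor did those for satellite cells (0.03), fibroblasts (0.00), endothelium (0.03), osteoclasts (0.14), Schwann cells (0.07), keratinocytes (-0.35, with the test pointing up) and dissociation stress (0.10). Of the sex linked list only Xist was abundant enough to test (-0.03).

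Called genes were not concentrated on chromosome 4, which held 4 of 56 (7.14%) against 6.05% of tested genes (Fisher's exact test, p = 0.581). The boundaries of the donor intervals are not in the labels, so genes were set against the whole chromosome and the intervals themselves were not tested. The 4 called genes on chromosome 4 were Klhl9, Abca1, Gdf6 and Tlr4, the last named after its value was seen and not called without the prefix term (adjusted p = 0.109). Chromosome 15 held 8 of the 56 calls, 14.3% against 3.91% of tested genes (Fisher's exact test, odds ratio 4.13, p = 0.00142, adjusted p = 0.0299). On it Srebf2, Sqle, Tnfrsf11b, Col2a1 and Tuba1b fell, and Lifr, AW549877 and Mettl7a1 rose. Without the prefix term 6 of these 8 were called, and Tuba1b (adjusted p = 0.142) and AW549877 (adjusted p = 0.0576) were not. Of 22 alternative settings, 15 ended the call of Col2a1, 14 each that of AW549877 and Mettl7a1, and 13 that of Tuba1b. The call of Lifr ended in 11 and that of Tnfrsf11b in 4, while Srebf2 and Sqle stayed called in all 22. The calls were spread along chromosome 15, at most 3 in a window of 10 Mb, and its share was not recomputed in the other settings. All B6 and ISRCL4 libraries carry the first title prefix, so these differences lie within 1 prefix. The count depended on single libraries: leaving out any 1 of the 10 except B6 replicate 3 (71 genes) left 12 to 33 genes, and DESeq2 called 238.

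In ISRCL3, Mstn rose 3.28-fold against B6 (log2 1.71 ± 0.193, adjusted p = 0.00119, edgeR's quasi-likelihood test), with 9.43 CPM in the 2 libraries of the first prefix and 9.44 in the 3 of the second. The osteocalcin gene Bglap2, a product of bone-forming cells, rose 2.99-fold (17.7 CPM in the first prefix, 15.8 in the second, 5.94 ± 1.41 in B6; adjusted p = 0.038). The metalloprotease gene Adam12 rose 2.45-fold (19.0, 18.3 and 7.77 ± 1.68 CPM in the same order; adjusted p = 0.038). The slow troponin gene Tnni1, a muscle-type gene, rose in the fit (2.05 ± 0.377, adjusted p = 0.0435). It stood at 28.8 CPM in replicate 2 and at 7.39 to 11.6 in the other ISRCL3 libraries. Of the 25 measured genes of the skeletal muscle fibre list 0 passed over all genes. The interferon-inducible gene Ifi208 (chromosome 1, 173673675 to 173698392) fell from 2.37 ± 0.47 CPM in B6 to 0.07 ± 0.10 in ISRCL3 (adjusted p = 0.0104), below the floor of 3 counts, with 1.20 ± 0.48 in ISRCL4.

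With the prefix term 37 genes passed, 32 higher and 5 lower in ISRCL3, and 1786 had an unadjusted p under 0.05. Without it 338 passed (271 higher, 67 lower), and 34 genes passed in both. Genes whose 5 libraries lay wholly apart numbered 717, 4.69% against 0.794% by chance. Nnt rose from 14.5 ± 2.57 CPM in B6 to 38.7 ± 2.89 in ISRCL3 (33.6 in replicate 4 of the second prefix and 39.2 to 40.7 in the other 4 libraries, adjusted p = 0.0104). Ide fell from 109 ± 8.87 to 52.9 ± 3.83 CPM (55.6 in the first prefix and 51.0 in the second, adjusted p = 0.00253). Wdfy1 rose (0.94 ± 0.103, adjusted p = 0.00119). Timd4, a phosphatidylserine receptor of macrophages, fell by 0.96 (5.58 and 5.26 CPM by prefix against 10.9 ± 1.62 in B6). The angiotensin receptor gene Agtr2 (1.34 ± 0.255), Ptprz1 (1.02 ± 0.183) and Edil3 (0.98 ± 0.188) rose. Wdhd1 (-0.57) and Mcm3 (-0.63), both of DNA replication, had an adjusted p of 0.0794 and 0.0822, and of 0.0322 and 0.0109 without the term. Tnni1, Adprhl1, Lmod2, Myl6b and Cdk5rap1 had log2 fold changes of 2.05, 1.91, 1.90, 1.74 and 1.41 with the term and 1.56, 1.47, 1.38, 1.29 and 0.93 without it, where Lmod2 (adjusted p = 0.0594) and Cdk5rap1 (adjusted p = 0.0593) were not called.

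Skeletal muscle fibre genes had a median log2 fold change of 1.16 in ISRCL3, and 0.71 without the prefix term. In edgeR 0 of 25 passed over all genes, 20 were higher and 1 lower at an unadjusted p under 0.05, and 20 were higher adjusted over the list alone (camera adjusted p = 4.048e-23; adjusted p = 0.1225 with an estimated correlation). The muscle score of ISRCL3 replicate 2 was 1.58, against 0.159 to 0.59 in the other ISRCL3 libraries and at most 0.379 in B6. Myh7, Myh2, Casq1 and Acta1 stood at 1.81, 1.77, 1.39 and 1.62. Without the term 12 members were higher and 1 lower adjusted over the list alone, and Myh7 passed over all genes (adjusted p = 0.0323). Satellite cell genes had a median of 0.29, with 0 of 17 called over all genes, 6 at an unadjusted p under 0.05 and 4 higher adjusted over the list alone, among them Des (0.55) and Myf6 (1.51), of which Myf6 passed over all genes without the term (adjusted p = 0.0408). The list passed camera (adjusted p = 7.965e-07; adjusted p = 0.1225 with an estimated correlation). Of 23 myostatin and activin genes Mstn alone passed over all genes, and 3 adjusted over the list alone (median 0.15, camera adjusted p = 6.147e-06; adjusted p = 0.1225 with an estimated correlation). Fstl1 (0.36, adjusted p = 0.285) passed as well without the term (0.39, adjusted p = 0.0418), where 2 passed adjusted over the list alone and the median was 0.12.

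Connective tissue and bone genes were higher as groups in ISRCL3 with camera's preset correlation. With the prefix term the fibroblast and osteoblast lists passed neither with an estimated correlation nor in directional fry (fry adjusted p = 0.0727 and 0.0521). In mixed fry both passed with the term (adjusted p = 0.01995 and 0.00828). Without the term both passed directional fry (adjusted p = 0.03168 and 0.03185) but not camera with an estimated correlation. Of 22 fibroblast and synovial lining genes edgeR called 0 over all genes, with 13 higher at an unadjusted p under 0.05 and 13 adjusted over the list alone (median 0.42). The list passed camera (adjusted p = 2.88e-12; adjusted p = 0.1225 with an estimated correlation), and without the prefix term the median was 0.43 and 10 rose over all genes. Cdh11, the cadherin of synovial fibroblasts, stood at 49.1 ± 5.61 CPM in B6 and 75.8 ± 12.7 in ISRCL3 (82.4 and 71.5 by prefix, adjusted p = 0.0528, and 0.0156 without the term). Of 11 osteoblast genes Bglap2 rose over all genes and 9 adjusted over the list alone (median 0.65, camera adjusted p = 2.149e-09; adjusted p = 0.1225 with an estimated correlation). The osteoblast median was 0.48 without the term, with 3 higher over all genes (Bglap, adjusted p = 0.0106, and Phex, adjusted p = 0.0418, besides Bglap2) and 6 higher and 1 lower adjusted over the list alone. Chondrocyte genes had a median of 0.50, with 0 of 13 called over all genes, 8 at an unadjusted p under 0.05 and 2 higher adjusted over the list alone, among the nearest Col11a1 (0.52) and Comp (0.46), which both passed over all genes without the term (adjusted p = 0.0343 and 0.0356). This list passed camera (adjusted p = 6.572e-07; adjusted p = 0.193 with an estimated correlation).

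Erythroid genes were lower (median -1.17, 4 of 10 adjusted over the list alone, camera adjusted p = 1.698e-07; adjusted p = 0.193 with an estimated correlation). Without the prefix term the erythroid median was -0.70 (camera adjusted p = 0.000612). Proliferation genes such as Mcm5 (-0.73) and Mki67 (-0.67) had a median of -0.46, with 4 of 16 lower adjusted over the list alone (camera adjusted p = 5.783e-09; adjusted p = 0.223 with an estimated correlation). Without the term 11 were lower adjusted over the list alone and 2 over all genes, Mcm5 among them (adjusted p = 0.00951). Leukocyte genes had a median of -0.39 (camera adjusted p = 0.00164; adjusted p = 0.514 with an estimated correlation). Both interferon lists had negative medians, -0.23 for type I and -0.28 for gamma, with 0 members called by edgeR, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Each passed camera and had an adjusted p of 0.514 with an estimated correlation. Klhl9 stood at 47.4 CPM in the first prefix and 37.8 in the second against 59.4 ± 3.55 in B6. Its log2 fold change was -0.33 (adjusted p = 0.157), and -0.51 (adjusted p = 0.00539) without the prefix term. The lists for osteoclasts (0.31), tendon (0.16), Schwann cells (0.31), keratinocytes (-2.27), cytokines (0.08), matrix proteases (0.27) and dissociation stress (0.22) passed with the preset correlation. Each was lost, with an adjusted p of 0.193, 0.467, 0.261, 0.592, 0.587, 0.193 and 0.24 with an estimated correlation. Without the prefix term the osteoclast list (median 0.10, camera adjusted p = 0.0735) and the keratinocyte list (camera adjusted p = 0.0513) did not pass. Of single members of these lists, Ctsk (adjusted p = 0.0136), Kera (adjusted p = 0.0185), Mmp2 (adjusted p = 0.0255), Mmp14 (adjusted p = 0.0198) and Hspb1 (adjusted p = 0.0323) were called as higher over all genes only in that fit. Chromosome 4 held 1 of the 37 calls, Pappa, named after its value was seen (2.70%, Fisher's exact test, p = 0.725). Without replicate 2 the fit with the term holds 1 first-prefix ISRCL3 library, and edgeR called 0 genes (901 with an unadjusted p under 0.05), while without that replicate and without the term it called 187. Without replicate 2 and with the term, the log2 fold change of Mstn ISRCL3 against B6 was 1.60 (adjusted p = 0.0755) and the log2 fold change of Ide ISRCL3 against B6 was -1.01 (adjusted p = 0.0755). Without replicate 1, with the term, it called 96. Without B6 replicate 1, 2, 3 or 5 or ISRCL3 replicate 5 it called 14, 12, 12, 23 and 20, and DESeq2 called 176 from all libraries.

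Between the lines, cartilage genes were lower in ISRCL4 and had the smallest camera p of the lists. Col2a1 was lower in ISRCL4 (46.1 ± 7.61 CPM) than in ISRCL3 (193 in the first prefix, 177 in the second), a log2 difference of -2.07 ± 0.339 (adjusted p = 0.0439, edgeR's quasi-likelihood test). Snorc, a cartilage proteoglycan, stood at -2.11, Col9a2 at -1.44, the cartilage link protein Hapln1 at -1.06 and Col11a1 at -0.81, and all passed. Of 22 alternative settings, 14 ended the call of Hapln1, 12 that of Col2a1, 11 that of Snorc and 10 each that of Col9a2 and Col11a1. None reversed the direction. All 13 chondrocyte genes were lower adjusted over the list alone and 5 over all genes, 13 without the prefix term (median -1.06, camera adjusted p = 5.71e-33), a call that held with an estimated correlation (adjusted p = 0.0202) and in fry (adjusted p = 0.00703). In the fit with the prefix term it was the 1 list call of the 3 comparisons that held with an estimated correlation, and in fry the tendon list between the lines held as well. Without the term the tendon list between the lines also held with an estimated correlation (adjusted p = 0.0467). In fry, 7 lists of ISRCL3 against B6 then passed (fibroblast, satellite cell, osteoblast, myostatin, matrix protease, chondrocyte and proliferation, adjusted p = 0.0317 to 0.0432), and 4 between the lines (chondrocyte, tendon, fibroblast and satellite cell). The keratinocyte list had a larger median between the lines (1.73) than the chondrocyte list, lost with the correlation estimated (adjusted p = 0.497 with an estimated correlation).

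With the prefix term 28 genes passed, all lower in ISRCL4, and 1793 had an unadjusted p under 0.05. Without it 670 passed (217 higher, 453 lower), and 27 genes passed in both. Genes whose libraries lay wholly apart numbered 1071, 7.0% against 0.794% by chance. Adam12 (-1.34 ± 0.228), the neural adhesion gene Chl1 (-0.97 ± 0.168) and the imprinted noncoding RNA Rian (-0.93 ± 0.168) were lower in ISRCL4. So was Cdk5rap1 (-1.25), which stood at 16.1 CPM in ISRCL3 replicate 2 and at 5.45 to 8.12 in the other ISRCL3 libraries and was not called without the term (adjusted p = 0.0831). With the term edgeR called 0 genes as higher in ISRCL4, and DESeq2 called 27. By p the nearest were Ifi208 (1.20 ± 0.48 against 0.07 ± 0.10 CPM, adjusted p = 0.0624), the glutathione transferase Gsta3 (10.9 ± 2.24 against 5.25 ± 0.85 CPM, adjusted p = 0.0807), Sord (0.47), Kifc2 (0.66) and Ino80b (0.60). Of these 5, all but Kifc2 (adjusted p = 0.052) were called without the term. Mstn did not differ detectably between the lines (-0.10 ± 0.189, adjusted p = 0.866), nor did Ptprc (0.35 ± 0.312, adjusted p = 0.686).

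Tendon genes had a median of -0.32 between the lines, with 0 of 10 called over all genes, 5 at an unadjusted p under 0.05 and 4 lower adjusted over the list alone; without the prefix term 5 were called over all genes. The list passed camera (adjusted p = 1.327e-09; adjusted p = 0.0887 with an estimated correlation) and fry (adjusted p = 0.0323). Fibroblast genes had a median of -0.37, with 0 of 22 called over all genes, 10 at an unadjusted p under 0.05 and 10 lower adjusted over the list alone. This list passed camera (adjusted p = 5.056e-10; adjusted p = 0.247 with an estimated correlation), Cdh11 (-0.66), Col6a1 (-0.57), Col5a1 (-0.52) and Col1a1 (-0.80) having the smallest p, and without the term 9 members, these 4 among them, were called over all genes. Skeletal muscle genes had a median of -0.89, with 20 of 25 lower and 1 higher adjusted over the list alone and 0 over all genes (camera adjusted p = 2.18e-13; adjusted p = 0.297 with an estimated correlation). Without the term the muscle median was -0.50, 0 members passed adjusted over the list alone in edgeR and 8 were lower and 1 higher at an unadjusted p under 0.05. The muscle score of ISRCL3 replicate 2, 1 of the 2 first-prefix ISRCL3 libraries, was 1.58. The type I interferon list had a median of -0.22, with 0 members called by edgeR, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.000246; adjusted p = 0.509 with an estimated correlation). As against B6, the type I list was thus called with the preset correlation and lost with an estimated one. The call of the type I list as lower in ISRCL4 therefore rests on the preset correlation alone, against B6 and against ISRCL3. Its single members differed between the comparisons. Against B6, 17 of 37 were lower adjusted over the list alone, and against ISRCL3 0 were. Leukocyte (median 0.38, camera adjusted p = 0.0029), erythroid (0.92, camera adjusted p = 8.191e-05) and proliferation genes (0.36, camera adjusted p = 6.394e-05) went the other way, with an adjusted p of 0.538, 0.457 and 0.476 with an estimated correlation. The other lists that passed with the preset correlation were lost too, with an adjusted p of 0.214 (satellite cells) to 0.554 with an estimated correlation. The erythroid (median 0.32), endothelial (0.04), myostatin (-0.08) and Schwann cell (-0.17) lists did not pass without the prefix term, with a camera adjusted p of 0.101, 0.253, 0.329 and 0.168. In that fit alone, Fstl1 (adjusted p = 0.0192), Alpl (adjusted p = 0.0474), Tnfrsf11b (adjusted p = 0.0099), Nos2 (adjusted p = 0.0294), Ccl19 (adjusted p = 0.0423) and Hspb1 (adjusted p = 0.0251) were called as lower in ISRCL4, and Fbxo32 (adjusted p = 0.0397), Lyve1 (adjusted p = 0.00818) and Lyz2 (adjusted p = 0.0316) as higher. Chromosome 4 held 1 of 28 calls, Col9a2 (3.57%, Fisher's exact test, p = 1). The count fell to 1 without ISRCL4 replicate 3 or 4, to 2 without ISRCL4 replicate 2 and to 5 without ISRCL4 replicate 1. It fell to 3 without ISRCL3 replicate 2 and to 6 without ISRCL3 replicate 5.

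**Figure D2:**
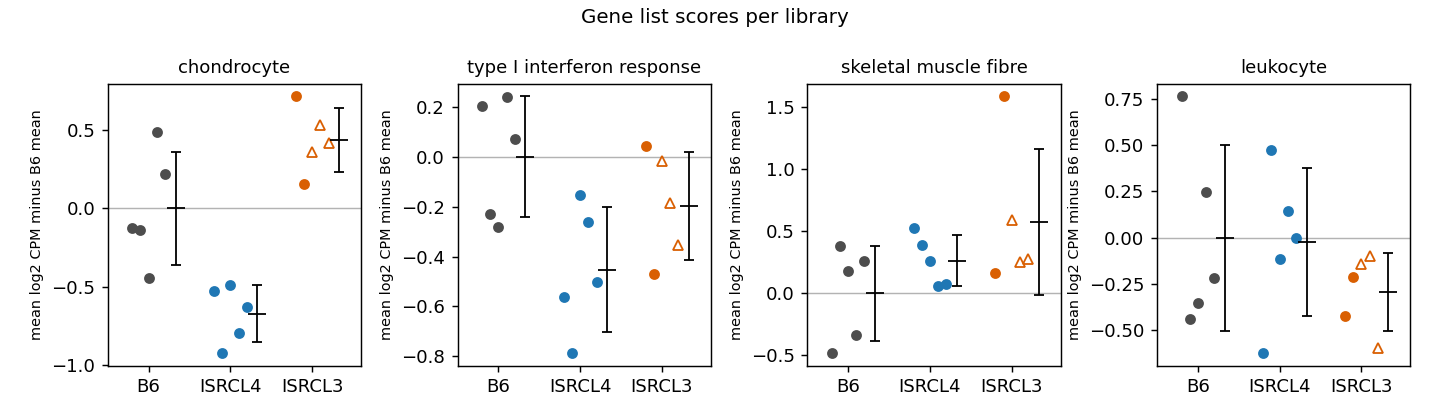
List scores per library (mean log2 CPM of the members minus the B6 mean, vertical axis) by strain for the chondrocyte, type I interferon response, skeletal muscle fibre and leukocyte lists; circles are libraries of the first title prefix, open triangles those of the second, and bars mean and SD. Chondrocyte scores averaged -0.674 ± 0.184 in ISRCL4 and 0.438 ± 0.208 in ISRCL3, and 1 ISRCL3 library stood at 1.58 on the muscle list.

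In both lines, Mstn, Wdfy1, Mme and Nnt rose and Ide and ENSMUSG00000094114 fell against B6. Independent calls would share 0.0418 rises and 0.0118 falls, a value that leaves out the shared B6 libraries, and 20 simulations of unchanged groups shared 0 each, a value that leaves out real effects. Neither is a chance value for these 6 genes, and part of them may come from the shared B6 libraries. With the B6 libraries divided 3 and 2 between the comparisons, 1 to 5 genes were called in both over 20 divisions. Each of the 6 separated all 10 congenic libraries from all 5 B6 libraries. Of all tested genes 57 did so, where chance gives 10.19. Calling a gene in both lines favours such a separation, so it adds no separate support for the 6. Without the prefix term 13 genes were shared, 9 higher and 4 lower.

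**Figure D3:**
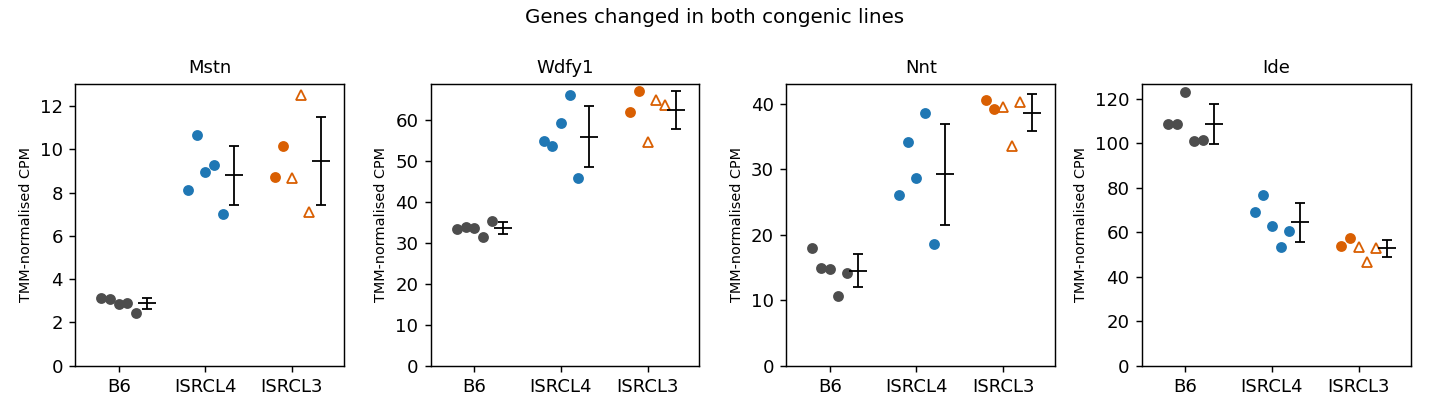
Scaled CPM per library (vertical axis) of Mstn, Wdfy1, Nnt and Ide by strain; circles are libraries of the first title prefix, open triangles those of the second, and bars mean and SD. The B6 libraries sit between 2.46 and 3.11 CPM for Mstn and the congenic libraries between 7.03 and 12.5.

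Across all genes the log2 fold changes of the lines against B6 had a Pearson correlation of 0.503, where simulated unchanged groups against the same B6 libraries gave 0.362 (0.309 to 0.414). The simulations drew each gene independently and hold no sets of genes that vary together between libraries, so their range may be too narrow here. The Spearman correlation was 0.345 against 0.343 simulated. Genes are not independent replicates, so no p is given. The covariance was 0.053 against 0.0206 simulated, and 61.7% of genes had the same sign against 62.2% simulated. When the B6 libraries were divided 3 and 2 between the comparisons the Pearson correlation averaged 0.0447 (-0.144 to 0.293 over 20 divisions). The covariance then averaged 0.00492 (-0.0208 to 0.0311). Agreement across all genes beyond the shared controls was therefore not shown. In the first prefix alone, with the B6 libraries shared, the Pearson correlation was 0.542.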

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

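The tests below on the prefix, the number of libraries, muscle content, inherited differences and other splits of the samples were set before their results were seen; the tests on the cartilage genes and the fit with a leukocyte score were chosen only after.

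Both lines shared a rise in Mstn and 5 other changes, which raises the question of tissue content against inheritance. Muscle fibre in the suspension is argued against as the whole cause: with the muscle score as a covariate the Mstn log2 fold change of ISRCL4 was 1.599 ± 0.169 (adjusted p = 0.00116), against 1.61 ± 0.157 without it, and that of ISRCL3 1.66 ± 0.252 (adjusted p = 0.0453). Inherited differences outside the selected interval remain a candidate explanation, since none of the 6 genes lies on chromosome 4. Of the 78 other tested genes within 2 Mb of them, 7 moved the same way in both lines at an unadjusted p under 0.05 (8.97% against 2.30% of other genes, Fisher's exact test, p = 0.002271), among them Hecw2, Fgf10, Ccl28, Ankrd1, Fgfbp3 and Btaf1. As background, C57BL/6J mice carry a known deletion in Nnt and a segment with Ide and Fgfbp3 is known to be duplicated in some C57BL/6J colonies, so a substrain difference between B6 and both lines may contribute; an effect of the selected interval on Mstn stays open and untested.

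Cartilage genes as a list were lower in ISRCL4 than in ISRCL3 (adjusted p = 0.0202 with an estimated correlation) and, with the preset correlation alone, lower than in B6 (adjusted p = 0.177 with an estimated correlation), and a smaller share of cartilage cells cannot be told apart from lower expression per cell. The 13 chondrocyte genes did not fall alike, from -1.84 for Col10a1 and -1.48 for Col2a1 to 0.04 for Comp (exact permutation p = 0.007937 for their spread around the common fall, the smallest that 5 against 5 libraries can give). A first test on Col2a1 relative to Acan alone gave a log2 difference of -0.64 (exact permutation p = 0.0159). Members that other joint cells also express, such as Comp and Sox9, would fall less under a lower share too, and 0 of the 13 rose, so unequal falls leave both explanations open, a reading settled after the value was seen. Loss of hypertrophic cartilage, the source of Col10a1, may add to the fall of that gene. It was not tested apart.

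The count in ISRCL3 against B6 was 37 with the prefix term and 338 without it. Fewer libraries may account for the gap: the 10 pairs of ISRCL3 libraries tested against B6 without the term gave 17 to 109 genes, all below the 225 (338 divided by 1.5) set as the bound. Counts from pairs would fall under a prefix batch too, so this does not tell the number of libraries from a batch. Whether the prefixes differ as a batch cannot be told apart from chance with 2 and 3 libraries. For genes changed in the second-prefix libraries, the fold changes in the first-prefix libraries against the other B6 libraries were 0.3191 to 0.827 times as large at the median over 10 divisions of B6, with 74.0% to 94.6% in the same direction. The prefix term itself passed for 0 genes in edgeR (805 at an unadjusted p under 0.05, 765 expected by chance).

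Other splits of the libraries were drawn, 100 for each comparison with the real one included. For ISRCL4 against B6, 3 of the 100, the real one included, gave at least the real 56 genes, a share under the 0.05 set beforehand. The highest other gave 224, so this share does not exclude chance. In the fit without the prefix term 4 of the 100 gave at least the real 53, and the highest other 286. The split with 224 set B6 replicates 1 and 4 with ISRCL4 replicates 2, 4 and 5, and such a count, several times the real one, points to a structure of the samples. The leukocyte scores of those libraries were 0.763, 0.246, 0.474, 0.143 and -0.002, and with a leukocyte score in the fit ISRCL4 against B6 gave 94 genes, 55 of them among the 56. For ISRCL3 against B6 only the real split gave as many as 37 (1 of 100, highest other 4). For ISRCL4 against ISRCL3 only the real split gave as many as 28 (1 of 100, highest other 24). Most of the 100 splits part the second-prefix libraries, which the real split does not, so these shares cannot exclude chance. In each of these 2 comparisons, only 16 of the 100 kept the second-prefix libraries together, of which the real split alone gave as many. These 16 are too few for a share under 0.05.

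In 18 of 216 sets of 5 libraries 1 library stood far from the other 4, its gap to the nearest exceeding 0.71 of the whole range, where chance gives 10.8. In ISRCL3, replicate 2 was highest for the muscle-type genes Tnni1 (28.8 CPM, gap 0.805), Lmod2 (18.9, gap 0.776) and Myl6b (19.1, gap 0.759) and for Cdk5rap1 (16.1, gap 0.749). Replicate 4 of ISRCL3 was lowest for the interferon cluster score (-0.115, gap 0.854), the osteoblast score (0.111, gap 0.803) and Nnt (33.6 CPM, gap 0.797), and replicate 1 for Aox1 (35.1 CPM, gap 0.738). In ISRCL4, replicate 4 had the highest total count (17717636, gap 0.746) and Myl6b (8.57 CPM, gap 0.711), and replicate 2 the highest mitochondrial share (4.64%, gap 0.80) and Fdft1 (13.2 CPM, gap 0.776). Fibcd1 was highest in ISRCL4 replicate 3 (1.03 CPM, gap 0.726). In B6, replicate 1 was lowest for Galnt15 (276 CPM, gap 0.769) and Adprhl1 (0.187 CPM, gap 0.735) and highest for Ifi208 (3.17 CPM, gap 0.755). Replicate 2 of B6 had the highest mitochondrial share (4.09%, gap 0.724) and replicate 3 the lowest Klhl9 (53.3 CPM, gap 0.714).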

How the results depend on the processing

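The leukocyte score and the libraries left out as standing apart (ISRCL3 replicate 2 for muscle, B6 replicate 5 and ISRCL4 replicate 1 for keratinocyte genes) were chosen after seeing the data. For ISRCL4 against B6 (56 genes) DESeq2 gave 238, only first-prefix libraries 26, only the strains compared 29, leaving out the libraries standing apart 23, that without the prefix term 33, and the leukocyte score 94; leaving out 1 library gave 12 to 71. For ISRCL3 against B6 (37) DESeq2 gave 176, no prefix term 338, only the strains compared 18, leaving out the libraries standing apart 0 in edgeR (939 at an unadjusted p under 0.05), that without the prefix term 102 (26 of the 37 among them), and the leukocyte score 14; leaving out 1 library gave 0 to 96. The 0 leaves replicate 1 as the lone first-prefix ISRCL3 library, assumed to vary like the others. For ISRCL4 against ISRCL3 (28) DESeq2 gave 194, no prefix term 670, limma voom 117, only the strains compared 16, leaving out the libraries standing apart 8, that without the prefix term 661, and the leukocyte score 8; leaving out 1 library gave 1 to 36. Without the prefix term and 1 library the counts were 18 to 73, 106 to 401 and 270 to 756. Dividing the B6 libraries took the correlation between the lines from 0.503 to 0.0447. The division ended the sharing of controls and also left fewer B6 libraries in each comparison, which were not told apart. Fewer samples lower the other counts in part, and otherwise the cause was not tested. Other size factors, both low-count filters and leaving out muscle and erythroid genes kept each count within 1.5 times. The genes called were less stable than the counts. With no low-count filter 38 of the 56, 30 of the 37 and 19 of the 28 stayed called. No gene or list call that was recomputed was reversed; genes and lists that were not called had no such run. Cyp51, Evi5l, Galnt15, Ide, Mstn, Sqle, Srebf2 and Wdfy1 stayed called in ISRCL4 against B6 in all 22 settings, and no chromosome 4 share changed its side of the threshold. Of 50 list calls with the prefix term 1 held with an estimated correlation, 2 in fry and 43 without the term; without it the tendon list between the lines held as well with an estimated correlation (adjusted p = 0.0467), and 7 lists of ISRCL3 against B6 and 4 between the lines passed fry. In simulated data 44% to 70% of 1.5-fold changes were recovered, so changes of that size can be missed.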

Other observations

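The 5 gene lists described here were written, and all tests on them chosen, only after the called genes were seen. Sterol synthesis enzymes were lower as a group in ISRCL4. Of 21 enzymes 8 fell over all genes (among them Cyp51, Sqle, Fdft1, Hmgcs1, Msmo1, Nsdhl and Hsd17b7) and 17 adjusted over the list alone, with a median log2 fold change of -0.39 (adjusted p = 0.00139 with an estimated correlation; fry adjusted p = 0.000179), tests that include the called enzymes that prompted the list. Srebf2 fell by 0.49, while the liver X receptor targets Abca1 (0.48) and Mylip (0.25), which act against uptake and storage, rose. That list of 10 had 2 rises over all genes and 3 adjusted over the list alone (median 0.09); it was written after those rises were seen, so no p is given for it. In ISRCL3 the sterol list had a median of -0.22, with 0 called by edgeR over all genes or adjusted over the list alone and 5 lower at an unadjusted p under 0.05 (adjusted p = 0.1001 with an estimated correlation; fry adjusted p = 0.0262); without the prefix term 7 were lower adjusted over the list alone (adjusted p = 0.0584 with an estimated correlation). The difference between the lines did not pass (adjusted p = 0.339 with an estimated correlation, and 0.207 without the prefix term), though without the term it passed fry (adjusted p = 0.0188).

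A hypothesis is that these enzymes moved as a pathway rather than as single genes. The 13 enzymes that did not pass singly had a median of -0.28 in ISRCL4 (camera p = 0.001431 with an estimated correlation). In ISRCL3 the same enzymes had a median of -0.22 (camera p = 0.0273 with an estimated correlation). These p-values are not adjusted. Both lines share the B6 libraries, so their agreement is not independent. Lower Srebf2 activity may be a candidate explanation, and the cause was not tested.

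Glucocorticoid target genes, a list written after some of them were seen as called, had positive medians in both lines. In ISRCL4 Klf15 rose over all genes and 8 of 16 adjusted over the list alone (median 0.32, adjusted p = 0.0389 with an estimated correlation). Klf15 was the only member called over all genes there, and 14 of 22 alternative settings ended its call. In ISRCL3 Klf9 (0.63 ± 0.121) and Ddit4 (0.52 ± 0.0943) rose over all genes and 7 adjusted over the list alone (median 0.55, adjusted p = 0.0616 with an estimated correlation; fry adjusted p = 0.0262), and without the prefix term 5 over all genes and 11 adjusted over the list alone (adjusted p = 0.0236 with an estimated correlation). These tests too include the called genes that prompted the list. The 13 targets that passed in neither line had medians of 0.29 in ISRCL4 (camera p = 0.04521 with an estimated correlation) and 0.56 in ISRCL3 (camera p = 0.0214). Higher glucocorticoid signalling in the congenic mice may be a candidate explanation; both lines share the B6 libraries, so their agreement is not independent, and hormone levels or the hour of collection are not analysed here.

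Immunoglobulin transcripts were lower in the lines as values. The list of 12 had medians of -1.06 in ISRCL4 and -1.86 in ISRCL3 (adjusted p = 0.177 and 0.148 with an estimated correlation), with 0 called by edgeR over all genes. At an unadjusted p under 0.05, 4 were lower and 1 higher in ISRCL4, all of them passing adjusted over the list alone, and 5 were lower in ISRCL3, none passing so. Without the prefix term 9 were lower in ISRCL3 adjusted over the list alone and 2 over all genes, Igkc among them (adjusted p = 0.0383), and the list had an adjusted p of 0.0584 with an estimated correlation. Igkc ranged from 94.7 to 708 CPM in B6 and from 26.7 to 72.7 in ISRCL3, although the suspensions were depleted of CD45-positive cells. Igha was the higher one, at 1.15 in ISRCL4 (adjusted p = 0.233 over all genes). The type 2 myeloid list did not pass in any comparison (medians 0.19, 0.47 and -0.03, the latter pair 1.03 and -0.68 without the prefix term).

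On chromosome 7, 3 unnamed transcripts within 36721846 to 36734558 rose in ISRCL3, Gm38340 by 2.38 and E230020A03Rik by 2.78 on the log2 scale (adjusted p = 0.0104 and 0.00271), and Gm37827 from 0.124 to 0.229 CPM in the B6 libraries to 0.887 to 1.59 (adjusted p = 0.0435). Gm42031 on chromosome 8 rose from 0 to 0.139 CPM in the B6 libraries to 0.808 to 2.08 in those of ISRCL3 (adjusted p = 0.00968), and its ISRCL4 libraries lay between 0 and 0.208. Most B6 values of Gm37827 and Gm42031 lay near or under the floor of 3 counts, so no fold is given for these. In ISRCL4, Gm38340 and E230020A03Rik stood at 1.11 and 0.73 and Gm37827 at 0.134 to 0.857 CPM, none passing. All 4 were named after their values were seen.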
